A study of Mus musculus with 7 samples.

How the data were processed

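The samples were mouse spleen-derived spi-1 transgenic erythroleukemic cells and spleen of strain DBA2J, per the labels. The labels give the same culture medium for all samples, with 5% serum and 1 U/mL of erythropoietin, the spleen samples included. Per the labels' protocols, DNA was sheared again to fragments of about 90 bp, ligated to adapters, selected at 150 to 200 bp and amplified for about 13 cycles. The genome build was mm9, per the submitters' processing notes. The aligner, the read filters and the peak caller with its settings are not given in the sources used here. Per the labels and the series' design text, reads of 2 mice were merged for the Spi-1 analysis and the input DNA of the ChIP experiments was pooled and sequenced as one control.

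The deposited read files list 1 aligned read per line. The score column of the deposited culture read files was 0 in every line and was not used; in the deposited spleen files it is a read score whose meaning no source gives. The deposited peak lists give each peak's start, end, position of the maximum and a height, which is the authors' own score. It was used only to rank and filter peaks within a list. Repeated positions (same chromosome, strand and 5' end) made up 17.3% of the 50-bp Spi-1 file, 7.96% of the 35-bp Spi-1 file and 0% of both spleen files, as would follow if repeated reads were removed from the spleen files before deposit. Reads were kept as deposited for the main values.

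Reads were counted by the middle of the aligned interval, with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with Matplotlib 3.10.9. Levels are reads scaled to the total of the library (RPM), and ratios carry a prior of 0.5 reads. Culture libraries were set over the culture input with both of its files summed, and the spleen library over the spleen input. Chromosomes 1 to 19 and X were used, which left out 24 RNA polymerase II peaks, 1 spleen Spi-1 peak and 186 H3K36me3 peaks. Random placement was of 2 kinds, each with 1000 draws: rotation of a list by a random offset within each chromosome, and positions drawn from input reads of the same chromosome. Shares carry 95% Wilson intervals and medians 95% bootstrap intervals from 2000 resamples of regions. Named peaks carry 99% conditional binomial intervals. Reads without molecular identifiers are not independent molecules, so all intervals cover counting error or the spread between regions only. No p-value was computed across peaks.

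Comparisons, tests and alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The regions named were chosen by a rule fixed at that point: the 5 highest peaks of each Spi-1 list, the 5 highest on one list alone with at least 4-fold more reads after scaling, and the 5 culture clusters with most peaks, leaving out peaks with input above 10 times the input median over peaks (13 culture and 11 spleen peaks). The text prints part of them. Depth outside peaks was compared between files in bins of 500 kb, leaving out reads within 1 kb of a peak; a segment was recorded where the running median over 5 bins passed 0.4 in log2 over at least 4 bins. A whole chromosome without such a segment was recorded where the quartiles of its bins lay apart from those of the input files. These comparisons were chosen after seeing the data.

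The functions were tested on simulated data. For 4000 simulated peaks of which a known part overlapped a second list, 42.4% were expected to overlap and 42.4% were counted. For 2400 simulated peaks with 400 planted triplets, 393 clusters of 3 or more were found. For 4000 simulated peaks with a true ratio of 3.85, the median ratio was 3.69. In the same simulation, narrow regions centred on input reads gave a median ratio of 0.828 where 0.962 was true, because such a region always holds at least 1 input read; regions 10 kb wider on each side gave 0.985.

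The position of peaks relative to genes, gene classes, marker gene lists and the Spi-1 sequence motif had also been planned. They need a gene annotation or sequence of mm9, which was not used here, and coordinates were not converted between builds.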

Results

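Spi-1 (PU.1) is an ETS-family transcription factor, and its overproduction in spi-1 transgenic mice gives rise to an erythroleukemia that can be grown from the spleen. Chromatin immunoprecipitation followed by sequencing was deposited for 7 samples. In cultured spleen-derived erythroleukemic cells, Spi-1, RNA polymerase II and H3K36me3 (a histone mark of the bodies of transcribed genes) were precipitated, with a mouse IgG control and input DNA. In samples labelled as spleen in vivo, Spi-1 was precipitated, with its own input; their labels also give the culture medium, so it is not clear whether these cells had been cultured. Each group holds 1 sample, so no difference between groups has a replicate check, and intervals cover counting error or the spread between regions only. The cultured Spi-1 sample joins reads of 2 mice and consists of a file of 35-bp reads and a file of 50-bp reads; the sources used here do not say whether each file is 1 mouse.

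The cultured Spi-1 sample held 30681331 aligned reads, of which 7762909 were in the 35-bp file and 22918422 in the 50-bp file. Its input held 32354837 reads. RNA polymerase II had 6099251 reads, H3K36me3 14068234 and IgG 5715950. In the spleen, Spi-1 had 13008312 reads and input 10986870. The deposited lists held 17781 Spi-1 peaks in culture, 12587 Spi-1 peaks in the spleen, 15947 RNA polymerase II peaks and 920506 H3K36me3 peaks. Positions are in genome build mm9. No gene annotation of that build was used here, so regions are named by position and not by gene.

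The first question was how strongly Spi-1 reads were concentrated at the called peaks. Over the 17781 culture peaks, Spi-1 reads scaled to library size were a median 3.84 times those of input (95% bootstrap interval over peaks 3.80 to 3.87). Over the 12586 spleen peaks that were used, the spleen Spi-1 library reached a median 3.05 times its own input (3.02 to 3.08). IgG lay at 1.13 times input over the culture peaks, and H3K36me3 at 0.971 times. RNA polymerase II lay at 1.47 times input over the same peaks. Culture peaks took up 5.79% of the cultured Spi-1 reads (95% Wilson interval 5.78% to 5.80%), 1.40% of IgG reads and 1.35% of input reads. The highest culture peaks included chromosome 11, 55343634 to 55345123, with 72.4 times input in culture and 25.4 times in the spleen, and chromosome 1, 51990855 to 51992631, with 54.5 times and 11.8 times. The peak at chromosome 18, 38509145 to 38510999, had 21.0 times input in both; it lies in a segment where the 50-bp Spi-1 file was 1.45 times deeper outside peaks than the 35-bp file, and had 18.4 times input in the 35-bp file and 21.7 times in the 50-bp file. Among the highest spleen peaks, chromosome 11, 20011428 to 20014235, reached 23.7 times input in the spleen and 28.5 times in culture, and RNA polymerase II there was 10.7 times input. Others were higher in the spleen library: chromosome 17, 3083478 to 3085021, had 7.84 times input in the spleen and 7.25 times in culture, with 2.92-fold more scaled reads in the spleen, and chromosome 18, 66596047 to 66598639, in the same segment of unequal depth, had 8.04 and 3.54 times, with 4.28-fold more. Both culture files showed enrichment separately, at a median of 3.98 times input for the 35-bp file and 3.74 times for the 50-bp file. Each list comes from the sample measured at it, so enrichment at its own peaks is in part built in. Across samples, the spleen Spi-1 library had a median 2.83 times its input over culture peaks. The culture Spi-1 library had 2.63 times its input over spleen peaks.

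**Figure D1:**
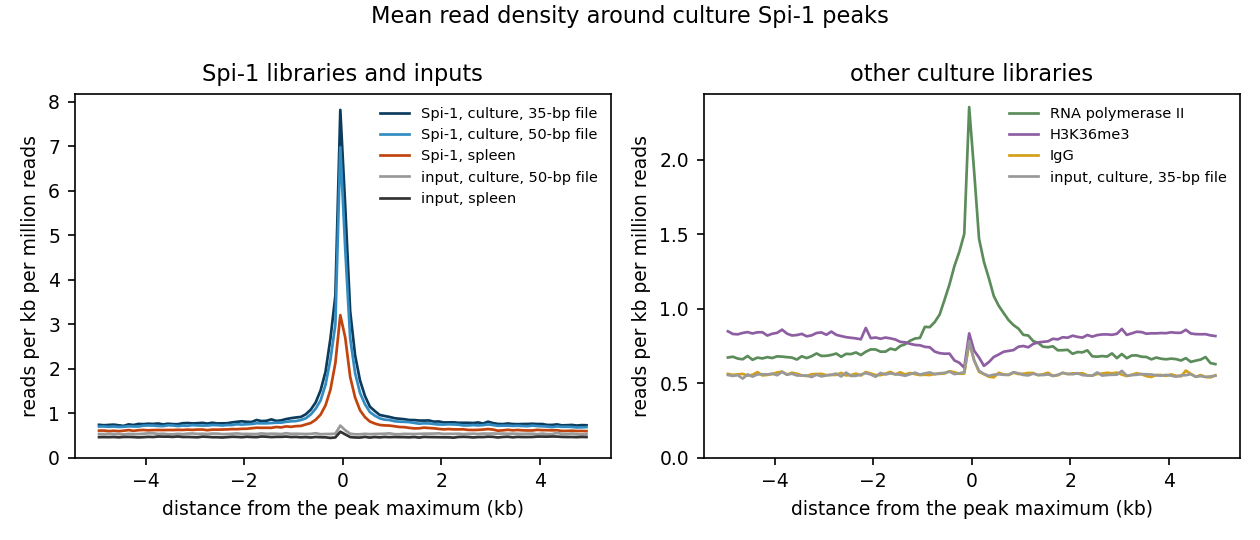
Mean read density, in reads per kb scaled to library size (RPKM), against the distance in kb from the maximum of each culture Spi-1 peak, in bins of 100 bp. The left panel holds Spi-1 libraries and inputs and the right panel the other culture libraries; just upstream of the maximum the 35-bp Spi-1 file reached 7.82, the spleen Spi-1 library 3.21, RNA polymerase II 2.35 and IgG 0.771, beside 0.784 for the 35-bp input file.

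The comparison of cultured cells with the spleen asked how many peaks were on both Spi-1 lists. Whether this compares culture with the animal depends on the spleen labels, which also name the culture medium. Of the spleen peaks, 7592 (60.3%, 95% Wilson interval 59.5% to 61.2%) overlapped a culture peak by at least 1 bp. Of the culture peaks, 8000 (45.0%, 44.3% to 45.7%) overlapped a spleen peak. When one list was rotated along each chromosome 1000 times, the mean overlap was 2.34% for spleen peaks and 1.71% for culture peaks, and the highest was 3.0% and 2.17%. Sharing rose with peak height. When each list was cut by height into 4 classes of equal size, 20.6% of the lowest culture class and 80.4% of the highest were shared, while for spleen peaks these shares were 29.0% and 92.9%. Shared culture peaks lay within 1 kb of an RNA polymerase II peak in 29.6% of cases (28.6% to 30.6%), against 19.9% (19.1% to 20.7%) of culture peaks absent from the spleen list. The polymerase was measured in cultured cells only.

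**Figure D2:**
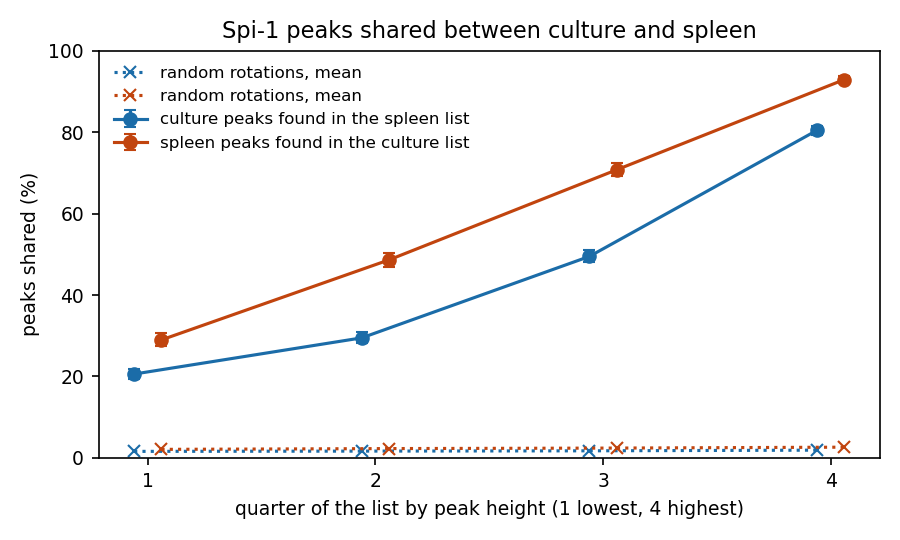
Share of peaks overlapping the other Spi-1 list, in percent, by height class (4 classes of equal size within each list), with 95% Wilson intervals as bars and the mean of 1000 random rotations as crosses. The highest classes reached 80.4% of culture peaks and 92.9% of spleen peaks.

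Read levels at the 22107 regions of the joined lists were lower in the spleen library, with a median log2 ratio of -0.51 (interquartile range -1.01 to 0.06). The median was -0.41 at the 7335 regions on both lists, -0.98 at the 9778 on the culture list alone and 0.52 at the 4994 on the spleen list alone. The lists were called from these samples, so the signs at regions on 1 list alone follow in part from how they were chosen. The median over all regions also depends on how many regions each list adds. With each library over its own input, a choice made after seeing the data, the overall median was -0.18. By the rule of at least 4-fold and 20 reads, 812 regions were higher in culture and 115 in the spleen. After centring on the regions of both lists, a choice made after seeing the data, the counts were 375 and 202. With a prior of 5 reads in place of 0.5 they were 132 and 93. Over own inputs they were 1239 and 234. The same rule applied between the 2 culture Spi-1 files gave 122 regions higher in the 35-bp file and 222 higher in the 50-bp file. Regions passing the 4-fold rule thus also occurred within the culture sample. Both counts were below the 812 regions higher in culture and above the 115 higher in the spleen. The 20 reads were not scaled to library size, so the rule is easier to pass in the deeper library of a pair. That is culture beside the spleen, and the 50-bp file beside the 35-bp file. The counts of the 2 pairs are thus not on one scale. At the 7335 regions on both lists, the rule gave 47 and 19 between the files. There it gave 35 higher in culture and 2 higher in the spleen.

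The highest peaks on the culture list alone included chromosome 6, 103103736 to 103105293, with 420 Spi-1 reads in culture and 6 in the spleen, a 29.7-fold difference after scaling (99% conditional binomial interval 11.2 to 117). Of these culture reads 413 came from the 50-bp file, where the peak had 30.4 times input, and 7 from the 35-bp file, with 1.42 times. The peak at chromosome 17, 65207354 to 65209298, was 9.10-fold higher in culture (5.09 to 18.2), and that at chromosome 11, 101282667 to 101283913, 7.31-fold higher (3.87 to 15.7); both were enriched in each culture file. Over own inputs they were 11.2 times in culture against 3.66 times in the spleen, and 11.4 against 1.33 times, so the spleen library also lay above its input at the peak on chromosome 17, from 19 Spi-1 and 4 input reads. On chromosome 19, the peaks at 41557575 to 41559262 and at 15997717 to 16000583 were 8.69-fold and 4.66-fold higher in culture. Over their own inputs these were 2.57 times in culture against 1.65 times in the spleen, and 3.82 against 2.15 times, and both lie in a segment where the 2 culture Spi-1 files differed in depth outside peaks. The culture input also differed from the spleen input there: from 14000001 to 47500000 its 50-bp file had 1.66 times the depth, and at the first of these peaks input was 4.67 RPM in culture and 0.819 in the spleen. In the 35-bp Spi-1 file the peaks had 8.14 and 10.2 times input, and in the 50-bp file 0.707 and 1.99 times. The peaks on the spleen list alone included chromosome 8, 55079133 to 55081016, which was 6.09-fold higher in the spleen (3.27 to 12) with 6.21 times its input there and 1.33 times in culture. A wide peak at chromosome X, 137583972 to 137588658, was 4.19-fold higher in the spleen (3.19 to 5.53), with 9.55 times input there and 2.46 times in culture. Chromosome X as a whole held 3.86% of spleen Spi-1 reads and 2.03% of cultured Spi-1 reads. From 136000001 to 139000000, around this peak, the spleen Spi-1 library had 1.40 times the depth of its input outside peaks. The peak at chromosome 11, 3023225 to 3025157, was 8.0-fold higher (5.20 to 12.7), but over own inputs it had 8.01 times in the spleen and 3.92 times in culture. These intervals compare the 2 libraries and not the 2 conditions.

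**Figure D3:**
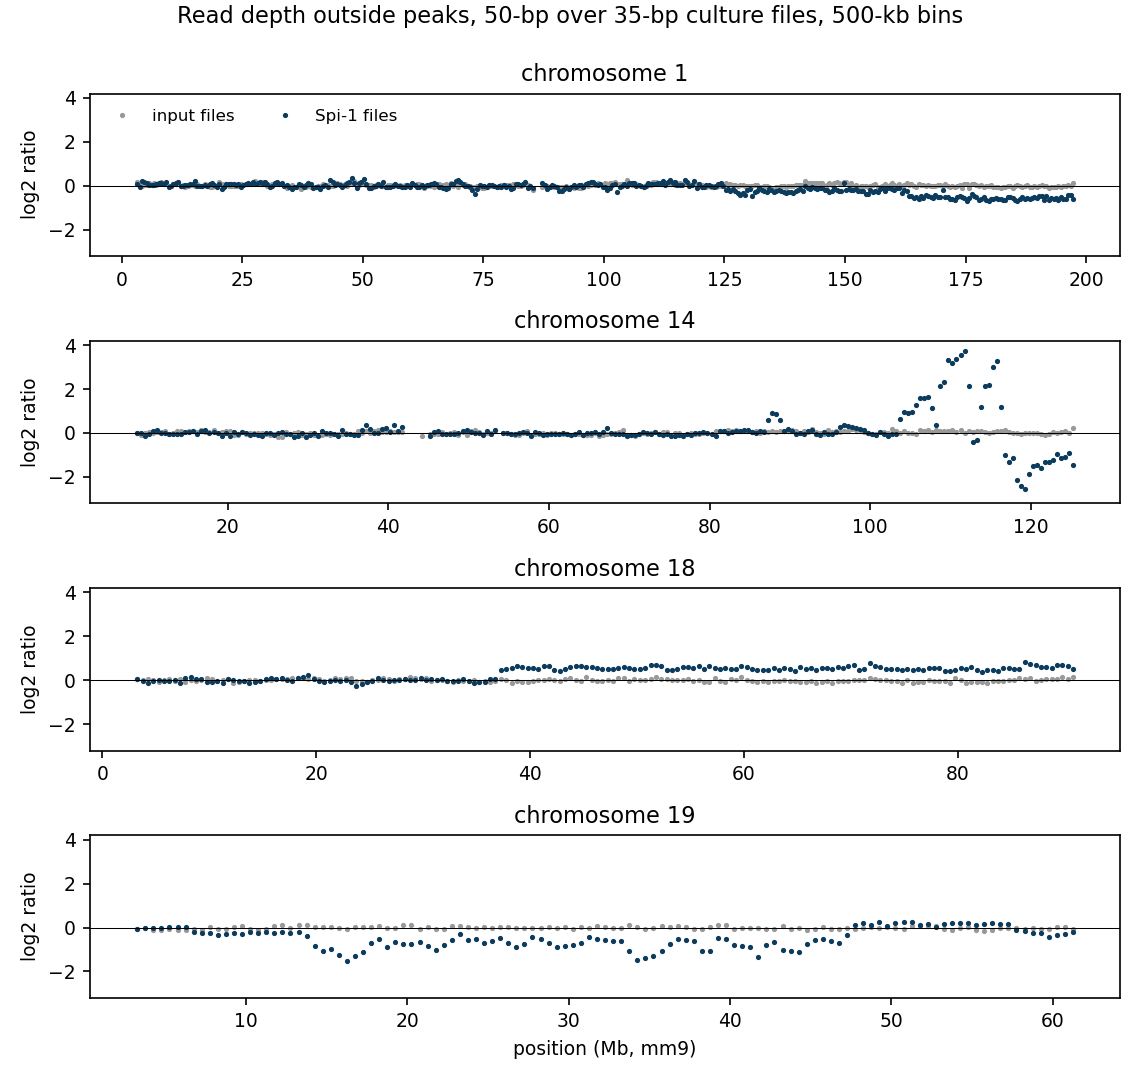
Log2 ratio of read depth outside peaks between the 50-bp and 35-bp files, in bins of 500 kb along chromosomes 1, 14, 18 and 19, in dark points for the culture Spi-1 files and grey points for the culture input files. Between 37000001 and 91000000 on chromosome 18 the Spi-1 files had a median ratio of 1.45, and the input files stayed near a log2 ratio of 0.

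The title of the series names clustered occupancy, and the spacing of peaks was compared with random placement. In culture, 8472 peaks (47.6%, 46.9% to 48.4%) had another Spi-1 peak within 10 kb. When the peaks were redrawn 1000 times at positions of input reads on the same chromosome, the mean was 18.2% and the highest 19.6%. There were 1114 clusters of 3 or more peaks with gaps up to 10 kb, holding 4154 peaks, beside a mean of 159 and a highest of 201 in the placements. In the spleen 38.7% of peaks (37.9% to 39.6%) had such a neighbour, beside 13.2% in placements, with 588 clusters of 3 or more. The clusters with most peaks were 10 peaks over 34.6 kb at chromosome 18, 62314998 to 62349568, of which 9 were shared with the spleen (in the chromosome 18 segment of unequal depth, with 3.09 times input in the 35-bp file and 4.55 times in the 50-bp file), and 10 peaks over 52.8 kb at chromosome 2, 169958216 to 170011039, with 10 RNA polymerase II peaks. A cluster of 9 peaks at chromosome 17, 35376098 to 35400177, held 9 RNA polymerase II peaks and had 2.71 times input for H3K36me3. Clusters of 9 peaks were also found at chromosome 10, 76660645 to 76696215, and chromosome 5, 104166764 to 104204444. Among peaks in clusters of 3 or more, 53.2% (51.6% to 54.7%) were shared with the spleen, against 39.9% (38.9% to 40.9%) of single peaks. The number of clusters depends on the distance chosen and on how many peaks are called: it was 610 with gaps up to 5 kb, 1867 with gaps up to 25 kb and 285 among peaks at or above the median height.

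Spi-1 peaks were next set against RNA polymerase II. Of the 30681331 culture Spi-1 reads, 22918422 came from the 50-bp file. Chromosome Y had 7.985 RPM in that file, beside 404 in the 35-bp Spi-1 file and 410 in RNA polymerase II. Whether most Spi-1 reads and the polymerase reads come from the same cells is thus not settled. Of the 15923 polymerase peaks used, 35.7% (34.99% to 36.5%) lay within 1 kb of a culture Spi-1 peak, and of the Spi-1 peaks 24.3% (23.6% to 24.9%) lay within 1 kb of a polymerase peak. Rotations gave means of 2.70% and 1.99%. Without the segments of unequal depth, a choice made after seeing the data, the observed shares were 36.8% and 24.3%. That does not show whether the cells were the same. The share of polymerase peaks near Spi-1 was 23.2% in the lowest of 4 height classes of polymerase peaks and 48.7% in the highest. The share of Spi-1 peaks near polymerase was 21.3% and 26.0% in the lowest and highest height classes of Spi-1 peaks. RNA polymerase II reads were 10.1 times input at polymerase peaks and IgG 1.31 times, from a median of 12 polymerase reads per peak. The polymerase peaks come from the same sample, so the first ratio is in part built in. Of the deposited polymerase peaks, 6538 had a height below the number in the name of their list, and 43.5% of the others lay within 1 kb of a Spi-1 peak.

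H3K36me3 was compared in the same way. Its library had 327 RPM on chromosome Y, so the same limit holds: most Spi-1 reads may come from other cells. Of the culture Spi-1 peaks, 60.7% (60.01% to 61.4%) touched an H3K36me3 peak, beside a mean of 35.7% and a highest of 39.2% in 1000 rotations. Within 5 kb of Spi-1 peaks H3K36me3 reads were a median 1.06 times input (1.05 to 1.07), beside 0.744 in regions of the same size centred on input reads. Spi-1 peaks near polymerase and touching H3K36me3 numbered 2877 (16.2%), those touching H3K36me3 only 7922 (44.6%), those near polymerase only 1436 (8.08%) and those with neither 5546 (31.2%). The share found in the spleen list was 56.4% (54.6% to 58.2%) in the first of these classes and 37.9% (36.7% to 39.2%) in the last.

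The last comparison asked whether regions with several Spi-1 peaks carried more RNA polymerase II and H3K36me3 than regions with 1. Here too, whether most Spi-1 reads come from the same cells as the other libraries is not settled. Within 10 kb of the 9309 single peaks, RNA polymerase II was a median 1.05 times input (95% bootstrap interval over regions 1.05 to 1.06), within 10 kb of the 2159 clusters of 2 it was 1.16 times (1.14 to 1.19), and within 10 kb of the 1114 clusters of 3 or more 1.28 times (1.25 to 1.31). H3K36me3 rose over the same classes from 0.971 times (0.956 to 0.99) to 1.25 (1.18 to 1.3) and 1.5 times (1.43 to 1.56). Clusters of 3 or more exceeded single peaks by a ratio of 1.22 (1.19 to 1.25) for RNA polymerase II and 1.55 (1.46 to 1.62) for H3K36me3. Random regions of the same sizes, drawn 1000 times, had means over the draws of 0.961 to 0.965 for RNA polymerase II and 0.741 to 0.753 for H3K36me3 in the 3 classes, and the draws lay between 0.946 and 0.981 and between 0.716 and 0.8. IgG was 1.02, 1.04 and 1.04 times input in the 3 classes. Peak height did not account for the difference: among peaks in the lowest of 4 height classes, RNA polymerase II was 1.3 times input (1.28 to 1.35) around those in clusters of 3 or more and 1.04 times (1.02 to 1.05) around single ones. In the highest class these values were 1.34 (1.29 to 1.38) and 1.06 times (1.04 to 1.07). Windows here reached 10 kb around each peak and not around each cluster. Those of peaks in 1 cluster overlap and share reads, so the intervals for clustered peaks are likely too narrow.

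**Figure D4:**
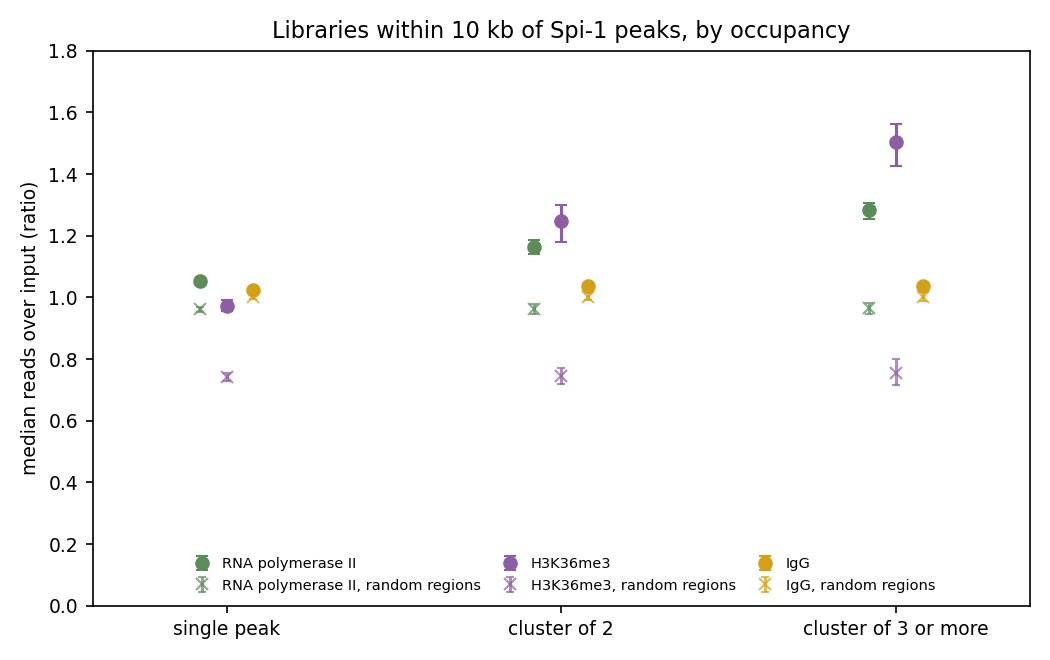
Median ratio of reads to input, both scaled to library size, within 10 kb of single Spi-1 peaks, clusters of 2 and clusters of 3 or more, with 95% bootstrap intervals over regions as bars; crosses are the mean of 1000 draws of random regions of the same size, with their lowest and highest as bars. RNA polymerase II rose from 1.05 to 1.28 and H3K36me3 from 0.971 to 1.5, while IgG stayed between 1.02 and 1.04.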

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

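Of the tests in this part, the one of reads far from peaks was set before its result was seen, and the others were chosen only after it. The 50-bp and the 35-bp culture Spi-1 files differed in read depth outside peaks in 7 segments and over the whole of chromosome 3. The planned analysis used reads outside peaks only for scaling, and did not compare them along chromosomes. Relative to the autosomal median, the 50-bp file had 0.683 times the depth on chromosome 1 from 163000001 to 197500000, 1.67 times on chromosome 14 from 87000001 to 89000000, 3.08 times from 103500001 to 116500000 and 0.402 times from 116500001 to 125500000. It had 0.631 times on chromosome 15 from 87500001 to 89500000, 1.45 times on chromosome 18 from 37000001 to 91000000 and 0.593 times on chromosome 19 from 14000001 to 47000000. Chromosome 3 lay under the limit for a segment but had 0.812 times the depth over 314 bins, with a median log2 ratio of -0.30 (quartiles -0.35 and -0.24) beside 0.02 between the input files. On chromosome Y, RPM (reads scaled to library size) was 7.99 in the 50-bp file and 404 in the 35-bp file, a ratio of 50.6, beside 451 and 477 in the input files, 446 in IgG and 410 in RNA polymerase II. It was thus the 50-bp file that departed from the other culture libraries. Over their own inputs, the 35-bp Spi-1 file showed none of the 7 segments, while the 50-bp file had 2.53 times the depth on chromosome 14 from 103500001 to 116500000, 0.389 times from there to 125500000 and 0.612 times on chromosome 19 from 13000001 to 45000000. It also had segments of 1.44 to 1.58 times on chromosome 18, 0.690 to 0.730 times on chromosome 1 and 0.636 to 0.752 times on chromosome 3, and others of 1.35 to 1.54 times on further chromosomes. Some of these others were not particular to the 50-bp file. The 35-bp file over its input had 1.35 times on chromosome 10 from 78500001 to 81000000 and 1.37 times on chromosome 11 from 115000001 to 120500000. The spleen Spi-1 library over its input had 1.57 times on chromosome 10 from 79000001 to 81500000. On chromosome 3 the 35-bp file lay below its input as well, with a median log2 ratio of -0.13 (quartiles -0.26 and -0.02).

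The tables argue against read length or chemistry, since over these segments the median absolute log2 ratio was 0.0225 between the 2 input files and 0.738 between the Spi-1 files. They argue against binding spread beyond peaks as well, since reads over 50 kb from every Spi-1 peak kept 0.684. Different chromosome content of the cells in the 2 files stays open. The chromosome Y ratio of 50.6, beside 0.946 between the input files, is part of what was first seen. It is no separate test. Over the spleen input, the 50-bp culture input had 1.64 times the depth on chromosome 15 from 87500001 to 89500000. On chromosome 19 from 14000001 to 47500000 it had 1.66 times. On chromosome 1 it had 1.43 times from 163000001 to 174500000 and 1.504 times from 176500001 to 197500000. On chromosome 14 from 118000001 to 122500000 it had 1.67 times. These places nearly match or lie within segments where the 50-bp Spi-1 file was lower. On chromosome 3, also lower in that file, the inputs had a median log2 ratio of 0.29. On chromosome 14 from 112000001 to 116500000, where that file was deeper, the input had 1.83 times. Such differences also lay outside the segments, as on chromosome 5 from 27000001 to 40000000, with 1.54 times. These values compare culture with spleen, not the 2 files, and do not settle it. Whether the files are the 2 mice named in the design text stays open too.

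Over input, the peak at chromosome 6, 103103736 to 103105293, lay above 1 in culture (22.7) and below it in the spleen (0.845). The spleen value rests on 6 Spi-1 and 6 input reads, too few to place it below 1. In culture 413 of 420 Spi-1 reads came from the 50-bp file, and the 35-bp file had 1.42 times input. The peak at chromosome X, 166444484 to 166445302, was noted because its values lay on opposite sides of 1, at 0.796 in culture and 1.02 in the spleen. These rest on 21 Spi-1 and 28 input reads, and on 47 and 39, too few to show a reversal. Neither difference was tested across samples, since each group has 1.

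Peaks on 1 list alone were weighed next. At the 9781 culture peaks absent from the spleen list, the spleen Spi-1 library still had a median 1.97 times its input (1.97 to 2.03), above the highest of 1000 sets of regions drawn from input reads (0.845) and of 1000 rotated sets (0.998; this second reference was added because the first lies low for narrow regions). This fits binding that may have fallen below the height threshold of the spleen list, but does not single it out. Over RNA polymerase II peaks the spleen Spi-1 library also had a median 2.20 times input, from a median of 5 Spi-1 and 2 input reads. Of those peaks 35.7% lie within 1 kb of a culture Spi-1 peak. The random regions were not matched for such places. The 4994 spleen peaks absent from the culture list had 1.49 times input in culture (1.47 to 1.51). Of the 9781 culture peaks, 8287 (84.7%, 84.0% to 85.4%) lay outside the 7 segments and chromosome 3, beside 86.8% of all culture peaks. These places hold only 2351 culture peaks, which argues against unequal depth there as the whole cause of the 9781 absences. The share lying outside follows from that number and decides nothing more. In the 7 segments 479 of 1458 culture peaks (32.9%, 30.5% to 35.31%) were shared, against 45.0% of all. How much of the pattern unequal depth accounts for stays open. Binding that differs between culture and spleen stays open, as untested.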

How the results depend on the processing

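With 1 sample per group, a value was called moved when it left the interval of the reported one. A count was called moved when it differed over 1.5 times. Of 87 alternatives, 50 moved and 37 did not. The sign changed in 0 of them, but only the median log2 ratio of spleen over culture could change sign. Shares, folds and ratios to input are always positive, and counts were not assessed for this. Settings marked "later" were chosen after seeing the data, and the cause was not tested unless given. Spleen peaks shared were 59.1% when a peak had to share at least 50% of the smaller one and 69.6% among peaks at or above the median height. The same settings gave 43.8% and 50.2% of culture peaks, and 46.1% without the segments of unequal depth (later; chromosome 3 was kept here and below). The fold over random placement was 25.8 by rotation and 21.8 with positions from input reads.

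Culture enrichment was 3.75 with 1 read per position, 3.98 and 3.74 with the 35-bp or 50-bp files only, 3.54 over IgG, 4.02 scaled by reads outside peaks and 3.91 without the segments (later). Spleen enrichment was 3.13 scaled by reads outside peaks.

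The median log2 ratio of spleen over culture was -0.43 with the 50-bp culture file, -0.54 scaled outside peaks and -0.31 with a prior of 5 reads. Later settings gave -0.10 centred on shared peaks, -0.18 over own inputs, -0.31 with highest-score spleen reads and -0.48 without the segments. Regions 4-fold higher in culture were 132 with the larger prior, which shrinks regions of few reads, 375 centred (later) and 1239 over own inputs (later). Those higher in the spleen were 202 centred, 234 over own inputs and 44 with highest-score reads (all later). Culture held 87.6% of such regions as reported, 58.7% with the larger prior and 65.0% centred.

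Peaks with a neighbour were 33.7% at 5 kb, 68.5% at 25 kb and 31.5% at or above the median height, with 610, 1867 and 285 clusters of 3 or more. The fold over placement was 2.62 as reported, 3.03 with uniform positions, and 3.05, 1.91 and 3.12 for those 3 settings.

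Polymerase peaks near Spi-1 were 27.6% by overlap, 47.7% within 5 kb, 25.6% among peaks at or above the median heights, 43.5% from the named height up (later) and 36.8% without the segments (later). In the other direction the first 4 of these gave 19.5%, 33.9%, 19.9% and 19.7%. Spi-1 peaks touching H3K36me3 were 57.8% with the higher H3K36me3 peaks, 72.4% with merged domains and 63.4% among higher Spi-1 peaks. Clusters over single peaks gave 1.27 for polymerase within 5 kb and 1.64 for H3K36me3 with gaps up to 25 kb. Using the 35-bp input file alone (later) gave 1.2 and 1.504. Alternatives for genes, gene classes, marker lists and the motif were not run, for want of an mm9 annotation or sequence. No paired analysis was possible because each group has 1 sample.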

Other observations

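As called, more RNA polymerase II peaks than Spi-1 peaks had another within 10 kb: 59.0% (58.3% to 59.8%), beside 16.4% in random placements. They were narrower, with a median width of 376 bp beside 1099 bp for culture Spi-1 peaks, and the largest cluster held 45. Whether broad sites cut into several calls add to this share was not tested for polymerase. Of the polymerase peaks, 45.6% touched an H3K36me3 peak, beside 24.6% in rotations. Spleen Spi-1 peaks touched culture H3K36me3 peaks in 72.7% of cases (71.9% to 73.4%), beside 43.7% in rotations, and 22.8% lay within 1 kb of a culture polymerase peak. Spleen peaks absent from the culture list were near a culture polymerase peak in 11.3% of cases (10.5% to 12.2%), against 30.4% (29.4% to 31.5%) of the shared ones.

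Clustering of Spi-1 peaks was tested against 2 explanations, both set before their results were seen. If it came from regional peak density alone, peaks redrawn from input reads within their own bin of 500 kb would keep the observed share of 47.6% with a neighbour. The highest of 1000 redraws was 35.4% and the mean 34.1%, so regional density does not account for all of the clustering. The redraws keep the count of peaks in each bin, which the clusters themselves raise, so they do not show what part it accounts for. If broad sites had been cut into several calls, merging peaks within 2 kb would end the excess. The 15759 merged peaks still had a neighbour in 35.03% of cases, beside a highest of 18% in placements. No biological explanation was tested.

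Chromosome X held 2.06% of reads in the 50-bp Spi-1 file and 1.95% in the 35-bp file, 3.86% in the spleen Spi-1 library and 3.31% in the spleen input. On chromosome Y the spleen Spi-1 library had 832 RPM and the spleen input 1720, and outside peaks the log2 ratio of the former to the latter was -0.88 on chromosome Y and 0.31 on chromosome X. The 50-bp culture input over the spleen input had a median log2 ratio of -0.54 on chromosome X, and 1.504 times the depth on chromosome 1 from 176500001 to 197500000. Of the culture Spi-1 peaks, 189 (1.06%) were on chromosome X, and of the spleen peaks 192 (1.53%). On chromosome 14 from 103500001 to 116500000, where the 50-bp file was deeper, the culture list had 42 peaks and the spleen list 8; of the 42, 7 were shared and 20 had under 2 times input in the 35-bp file.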
